A study of Mus musculus with 117 samples.

How the data were processed

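The 117 libraries are RNA-seq of mouse adipocyte cultures and white adipose tissue. The cultures are 21 wild-type and 24 labelled HuR KO or control. The tissues are 24 from mice titled FKO-HuR (here HuR KO) and controls, and 48 from mice titled AP2-HuR and controls. RNA was extracted with TriZol and a miRNeasy kit, and strand-specific libraries were made and sequenced by a service company, per the labels' protocols. Adapters were trimmed with cutadapt, reads were aligned with STAR to the mm10 build and counted per gene with featureCounts, per the submitters' processing notes, which give no versions and do not say whether counting used strand. The deposited files hold 1 value per gene symbol, without a header line, and the values are log2(TPM + 1): turned back to TPM, each library sums to 937015.1 to 997540.8. No note states how the authors made TPM from counts or which genes they left out. In the deposited tables every gene reaches 1 TPM in at least 9 of 21 wild-type culture libraries, 6 of 12 in each other culture table and 18 of 24 in each tissue table. Genes below these levels are therefore missing, also where only 1 small group expresses them.

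The tables hold 14465 genes (wild-type cultures), 14901 and 15513 (insulin and Torin cultures of the HuR KO experiment), 13319 (HuR KO tissues), 14640 (AP2-HuR iWAT) and 15417 (AP2-HuR eWAT). Among the HuR KO tissue values, 20 entries named by a number only were left out. No pair of libraries was identical, and the highest correlation between any pair was 0.9928. Read totals are not in the files used here. They were estimated from the spacing of low TPM values with exon lengths of the GENCODE M21 annotation (mm10): in each library 95.71% to 99.31% of low values were whole read numbers within 0.1. The estimates, in M reads, are 30.36 to 43.84 for the nutrient cultures, 32.53 to 45.3 for the first insulin cultures, 66.76 to 86.42 and 66.46 to 125.79 for the insulin and Torin cultures of the HuR KO experiment, 18.86 to 45.36 for HuR KO tissues and 50.54 to 79.02 for AP2-HuR tissues. Expression was not tested on recovered reads, and their totals enter only a test of depth in the AP2-HuR libraries.

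The design fixed before the files were seen named a quasi-likelihood test on counts. Because the values are not counts, limma was used instead (version 3.58.1, R 4.3.3; linear fits with moderated variances and a mean trend) on log2(TPM / factor + 1). The factor of each library is a trimmed mean of log ratios, with 30% of log ratios and 5% of mean levels trimmed at each end, without weights. TPM of a gene in the text is divided by this factor. Genes entered a fit with at least 1 TPM in as many libraries as its smallest group has. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 is a call. All p-values are from limma unless another test is named, and all are 2-sided. Tables were never compared in level. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and figures.

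Of the 27 comparisons, those of the nutrient experiment share 1 fit of 15 libraries with time as a factor, and their 4 arms share 3 control libraries. The first insulin experiment is a fit of 6 libraries, and the insulin and Torin experiments with cells labelled HuR KO are fits of 12, all with time as a factor. Because cultures have 1 library per arm and time, a response that changes with time counts as spread. Each tissue and experiment is a fit of 4 groups, from which fasting in controls, the genotype label in each state and their interaction were tested. Of 36 gene lists fixed beforehand, the 29 to 35 with at least 2 members measured in a table were tested, where camera with a preset correlation of 0.01 compared each list with all other genes, and the adjusted p with a correlation estimated from the libraries is given beside each list.

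Genes named are Elavl1, the 6 largest and 6 smallest log2 fold changes among called genes with a mean of at least 4 TPM (without symbols of predicted genes, clones and small RNAs of the Gm, Rik, Mir and Snor kinds), up to 4 members of a called list with the smallest p, up to 2 of another list mentioned, and genes fixed for each kind of comparison. Some genes that this rule picks are not reported here. Other genes are said to be chosen after their values were seen: these are A430018G15Rik, the genes shared by the comparisons of groups labelled HuR KO, p53 targets, and those of the splits and strand checks. Genes with near-identical copies (histones, Prl2c, Ifit3 and Ifit3b, immunoglobulin segments) and genes overlapping another on the opposite strand are uncertain, since reads could be counted for either.

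Whether replicate numbers pair the tissues was checked from correlations of deviations from group means. For labelled HuR KO in ad libitum iWAT same-numbered libraries correlated at 0.48 to 0.77, for AP2-HuR at 0.16 to 0.54 in ad libitum iWAT, 0.37 to 0.55 in fasted iWAT and 0.20 to 0.73 in fasted eWAT, so that numbers were taken to pair these. In the other 8 comparisons at least 1 pair correlated below 0.1. The labels do not say what a number stands for.

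Alternatives were another scaling, no scaling, no filter or a higher one, other pseudocounts, fits of only the groups compared, no time term, a replicate block, each library or time left out in turn, and the AP2-HuR replicates 1 to 3 and 4 to 6 apart. Up to 100 regroupings of the libraries were fitted per comparison. The scripts were tested on simulated data, with 200 genes changed per size in each design. A log2 change of 2 was recovered for 56.1% to 100% of genes and one of 1 for 1.49% to 97%. There were 0 with the wrong sign and at most 14 false calls. A shifted list was called in 27 of 27 comparisons against 0 of 873 tests of other lists. Genes were simulated as independent, so false list calls from correlated genes were not measured. Isoform usage, the subject of the series' title, was not analysed here, since the values are per gene.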

Results

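The series holds 117 RNA-seq libraries of mouse adipocytes and adipose tissue. Cultured adipocytes were deprived of amino acids or glucose, treated with AICAR (an activator of AMP-activated kinase) or Torin (an inhibitor of the mTOR kinase), or stimulated with insulin after a fasting medium. Further cultures labelled HuR KO or control received insulin or Torin. The tissues are inguinal (iWAT) and epididymal (eWAT) white fat of ad libitum fed and fasted mice. They come from mice titled FKO-HuR (here HuR KO) or AP2-HuR, and from the controls of each. HuR, encoded by Elavl1, is an RNA-binding protein that binds AU-rich elements of messenger RNAs. In the cultures each arm has 1 library per time point, so that 3 times stand in for 3 replicates. The tissues have 3 libraries per group in the HuR KO experiment and 6 per group in the AP2-HuR experiment. Values are per gene, and isoform usage was not analysed. In what follows, a number in brackets after a gene is its log2 fold change ± standard error of the fit, and "rose" and "fell" mean an adjusted p under 0.05, adjusted within a gene list for counts over the list alone.

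Elavl1 was not lower in any group labelled HuR KO than in its controls. In the insulin cultures it was 25.8 to 26.6 TPM in the 3 medium libraries labelled HuR KO against 20.3 to 20.7 TPM in control cells. With insulin the values were 26.6, 30.7 and 33.7 TPM against 23.3, 26.8 and 30.4 TPM. Elavl1 was higher in 6 of 6 time-matched pairs there (0.25 ± 0.06, adjusted p = 0.0209). In the Torin cultures it was also higher in 6 of 6 pairs, by less (0.15 ± 0.10, adjusted p = 0.516). In iWAT the difference was 0.13 ± 0.12 in the ad libitum state (adjusted p = 0.919, higher in 1 of 3 same-numbered pairs) and 0.46 ± 0.12 fasted (adjusted p = 0.241, 3 of 3 libraries above the control mean). In eWAT it was 0.06 ± 0.07 in the ad libitum state (adjusted p = 0.883, 2 of 3) and 0.38 ± 0.07 fasted (adjusted p = 0.0373, 3 of 3). Because these values show no loss, the groups, FKO-HuR included, are called "labelled HuR KO", and each direction given for them is between labels. Gene-level values cannot tell whether part of the gene was deleted while reads from the rest were still counted. Whole tissue also mixes cell types, so a loss in adipocytes alone stays open there.

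Elavl1 was far higher in every AP2-HuR library than in its controls. In ad libitum iWAT the 6 AP2-HuR libraries held 30.4 to 68 TPM against 16.2 to 18.2 TPM (1.42 ± 0.13), and in fasted iWAT 85.9 to 104 TPM against 15.8 to 18.5 TPM (2.44 ± 0.13). In eWAT the ad libitum libraries held 38.6 to 69.1 TPM (1.61 ± 0.09) and the fasted ones 121 to 141 TPM (2.81 ± 0.09), with controls at 16.6 to 18.2 TPM over both states. The gain from fasting within AP2-HuR eWAT passed the test of the interaction (1.20 ± 0.13, adjusted p = 7.46e-05), while that in iWAT was 1.02 ± 0.18 with an adjusted p of 0.0688.

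**Figure D1:**
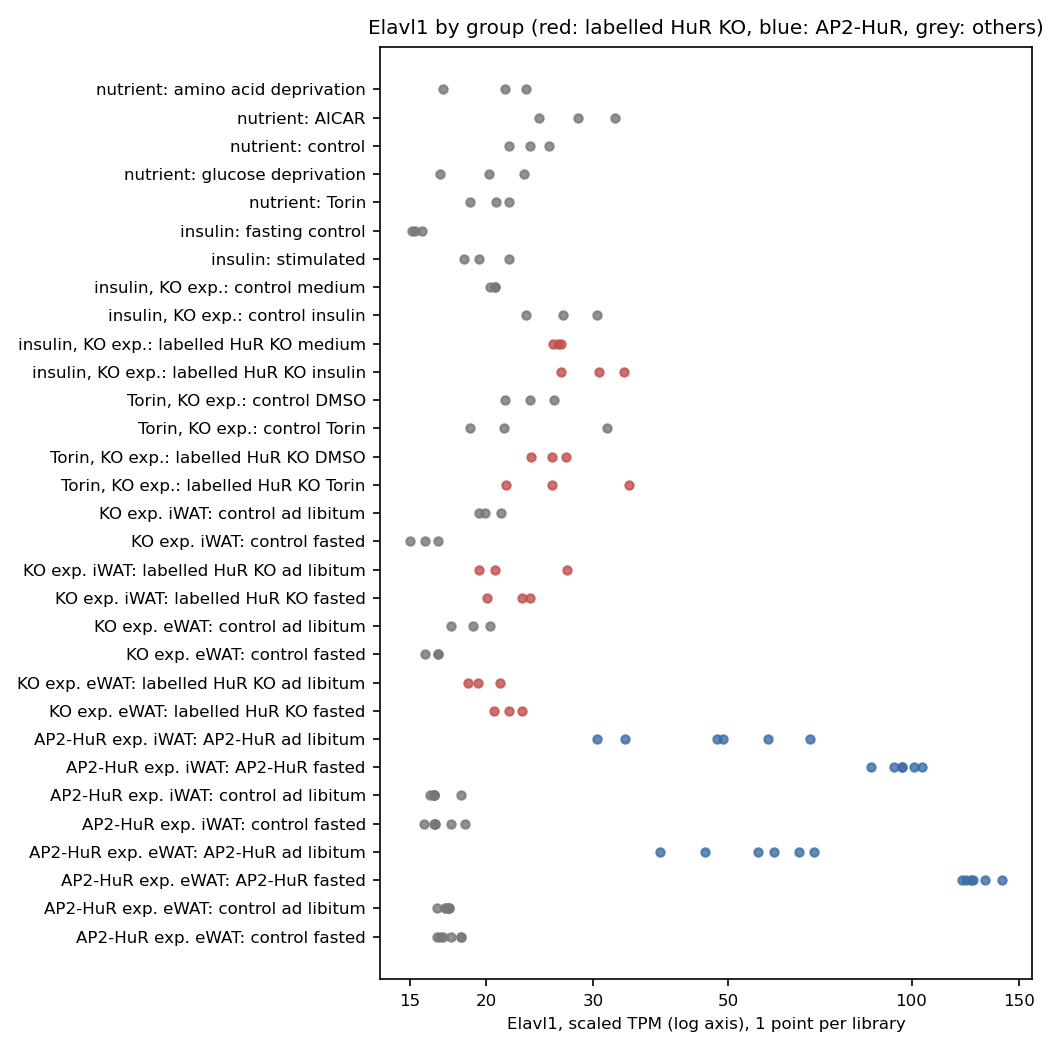
Elavl1 in scaled TPM (log axis) in each library, 1 point per library, by group of the 6 tissue and culture experiments. Groups labelled HuR KO overlap or exceed their controls, and AP2-HuR libraries lie at 30.4 to 141 TPM.

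Under amino acid deprivation the hypoxia-induced genes were higher together, though no single gene passed the genome-wide test. Of 20 hypoxia-induced genes, 19 were higher when adjusted over the list alone and 0 over all genes (median log2 fold change 1.01, adjusted p = 0.118 with an estimated correlation). Values include 2.27 ± 0.41 for Ankrd37, 1.56 ± 0.24 for the histone demethylase Kdm3a, 0.94 ± 0.17 for the collagen prolyl hydroxylase P4ha2 and 1.17 ± 0.21 for the vessel peptide Adm. Glycolysis went the same way, with 7 of 19 genes higher adjusted over the list alone and 0 over all genes (adjusted p = 0.327 with an estimated correlation), among them the lactate exporter Slc16a3 at 1.74 ± 0.43 and the glucose transporter Slc2a1 at 1.32 ± 0.32. Cholesterol synthesis genes were lower (12 of 25 over the list alone, 0 over all genes, adjusted p = 0.118 with an estimated correlation). So were ribosome biogenesis factors (14 of 35 over the list alone, 0 over all genes, adjusted p = 0.28 with an estimated correlation). Genes of the amino acid response were lower as a list too: the median was −0.23 over 39 genes (1 higher and 1 lower over the list alone, adjusted p = 0.754 with an estimated correlation). Asparagine synthetase Asns was at −0.33 ± 0.20 and Trib3 at −0.64 ± 0.31. Elavl1 was at −0.20 ± 0.15.

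Limma called 0 genes over the 3 time-matched pairs, with 1897 of 14462 at an unadjusted p under 0.05 against 723 from chance. Fitted on the 6 libraries of these arms alone, the same model called 265.

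Glucose deprivation gave no gene past the test. Interferon-stimulated genes had a median of 1.04 over 22 genes, with 0 past the test over the list alone and an adjusted p = 0.834 with an estimated correlation. In arms that share these controls it was 0.69 (amino acid deprivation), 0.77 (Torin) and −0.04 (AICAR). The antiviral genes Ifit1 and Rsad2 were at 1.92 ± 0.80 and 1.62 ± 0.59. Txnip, which rises with glucose uptake in many cells, was at −0.59 ± 0.53 and Elavl1 at −0.23 ± 0.15. Limma called 0 genes, and 305 had an unadjusted p under 0.05, fewer than the 723 from chance. In the 6 h library of this arm a single transcript, the ribosomal RNA fragment Gm23935, held 40.4% of all TPM, and in the 12 h library mitochondrial transcripts held 0.81%.

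AICAR moved more genes than any other nutrient arm, with 2402 higher and 2517 lower. The genes that rose most include Fnip2 (2.90 ± 0.19) and Ifi207 (2.88 ± 0.47), the stress factor Atf3 (2.67 ± 0.56), and the kinase phosphatases Dusp10 (2.67 ± 0.43) and Dusp5 (2.64 ± 0.37), with the small nuclear RNA Rn7sk (2.96 ± 0.49). Those that fell most are Gmppb (−3.07 ± 0.18), Rgs4 (−2.89 ± 0.33), the gap junction protein Gjb2 (−2.65 ± 0.51), Amotl2 (−2.60 ± 0.19), Rin1 (−2.55 ± 0.25) and Lmod1 (−2.49 ± 0.30). Of the lysosome and autophagy genes driven by TFEB, 16 of 30 measured rose (20 over the list alone, adjusted p = 0.326 with an estimated correlation). They include the lysosomal nutrient sensors Flcn (1.54 ± 0.27), Fnip1 (2.08 ± 0.29) and Rragc (1.45 ± 0.21). Of immediate early genes 20 of 32 measured rose and 1 fell (21 and 2 over the list alone, adjusted p = 0.326 with an estimated correlation), with Klf6 (1.75 ± 0.13), Myc (1.67 ± 0.22) and Fos (1.32 ± 0.17). Of clock genes 9 of 17 measured rose (10 over the list alone, adjusted p = 0.326 with an estimated correlation), led by Arntl (1.72 ± 0.21). Of the transcripts described as bound by HuR, 14 of 26 measured rose and 5 fell (14 and 5 over the list alone, adjusted p = 0.326 with an estimated correlation), among them Il6 (1.91 ± 0.31) and Mcl1 (1.54 ± 0.15). Elavl1 itself was at 0.25 ± 0.15 (adjusted p = 0.213).

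More amino acid response genes fell than rose with AICAR: 4 of 39 measured rose and 16 fell (4 and 17 over the list alone, adjusted p = 0.702 with an estimated correlation). Chac1 (−2.39 ± 0.18), which degrades glutathione, Sesn2 (−1.19 ± 0.14) and the hormone Fgf21 (−1.82 ± 0.32) fell, while Cebpg (1.00 ± 0.18) rose. Of cell cycle genes 16 of 28 measured fell (22 over the list alone, adjusted p = 0.694 with an estimated correlation), with Cdc20 (−2.06 ± 0.46). Of chaperones of the endoplasmic reticulum 9 of 19 measured fell (11 over the list alone, adjusted p = 0.326 with an estimated correlation), and of matrix genes 8 of 26 measured fell (8 over the list alone, adjusted p = 0.694 with an estimated correlation), with Timp1 (−1.42 ± 0.23) and the collagen Col1a1 (−1 ± 0.27). Of macrophage markers 1 of 11 measured rose and 4 fell (1 and 6 over the list alone, adjusted p = 0.556 with an estimated correlation). The count of 4919 ranges from 928 without the 6 h libraries to 5785 without the AICAR library of 3 h. Without scaling of the libraries 750 genes were higher and 2025 lower.

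Torin in wild-type adipocytes raised 734 genes and lowered 956. Pdk4 (3.31 ± 0.83), which shuts off pyruvate oxidation, the lipid droplet protein Plin2 (2.22 ± 0.41), Acer2 (2.17 ± 0.50), Cyp4b1 (2.12 ± 0.34), Ifi207 (2.20 ± 0.47) and Scarna17 (2.86 ± 0.65) rose most. The insulin receptor substrate Irs2 (1.72 ± 0.36), Txnip (2.05 ± 0.53) and the autophagy receptor Sqstm1 (1.19 ± 0.24) rose as well, as did the adipocyte regulator Pparg (1.22 ± 0.24). Among the genes that fell most are those that make or import amino acids and one-carbon units, Cth (−2.91 ± 0.54), Slc1a4 (−2.59 ± 0.38), Slc7a5 (−2.49 ± 0.41), Mthfd2 (−2.34 ± 0.31) and Psat1 (−2.30 ± 0.39). Of amino acid response genes 1 of 39 measured rose and 26 fell (2 and 31 over the list alone, adjusted p = 0.517 with an estimated correlation). Of endoplasmic reticulum chaperones 16 of 19 measured fell (17 over the list alone, adjusted p = 0.0408 with an estimated correlation), the one list of this experiment whose call held. Of cholesterol synthesis genes 13 of 25 measured fell (20 over the list alone, adjusted p = 0.279 with an estimated correlation), of cell cycle genes 12 of 28 measured fell (24 over the list alone, adjusted p = 0.659 with an estimated correlation), and of TFEB genes 9 of 30 measured rose (11 over the list alone, adjusted p = 0.552 with an estimated correlation). Elavl1 was at −0.20 ± 0.15 (adjusted p = 0.41). The count of 1690 ranges from 0 without the 6 h libraries to 1621 without the Torin library of 3 h, and is 5 from the 6 libraries of these arms alone and 404 with no time term. It is 240 without the libraries in which Gm23935 took 40.4% and 30.3% of TPM. Without scaling 139 genes were higher and 456 lower.

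Insulin raised 312 genes and lowered 316 in wild-type adipocytes, from 3 libraries per arm at 1, 2 and 4 h. Mitochondrial transcripts held 1.23% of TPM with insulin at 4 h against 12.7% in its control, and Gm23935 held 22.55% in that control and 17.06% with insulin at 2 h. Angptl8 (4.31 ± 0.24), a lipoprotein lipase inhibitor induced by feeding, rose most. Ppp1r3b (3.02 ± 0.22), which targets a phosphatase to glycogen, Lcn2 (2.60 ± 0.27), the prostaglandin E synthase Ptges (2.54 ± 0.28), Mid1ip1 (2.51 ± 0.14) and Bhlhe40 (2.34 ± 0.11) followed. Pdk4 (−2.80 ± 0.44), the atrophy ligase Fbxo32 (−2.29 ± 0.16), the phosphoinositide kinase inhibitor Pik3ip1 (−2.23 ± 0.27), the death gene Bmf (−2.20 ± 0.18), Mmp11 (−2 ± 0.27) and AC107711.1 (−2.43 ± 0.18) fell most. Of ribosome biogenesis factors 14 of 35 measured rose (30 over the list alone, adjusted p = 0.68 with an estimated correlation). Of cholesterol synthesis genes 10 of 25 measured rose (22 over the list alone, adjusted p = 0.68 with an estimated correlation). Of immediate early genes 9 of 32 measured rose (17 over the list alone, adjusted p = 0.68 with an estimated correlation), with Fosl1 (2.13 ± 0.18) and Ier2 (1.85 ± 0.13), and Egr1 was at 0.97 ± 0.29 (adjusted p = 0.104). Of FOXO targets 10 of 23 measured fell (14 over the list alone, adjusted p = 0.68 with an estimated correlation). Fasn, the fatty acid synthase, was at 2.79 ± 0.58 (adjusted p = 0.0595) and Elavl1 at 0.35 ± 0.12 (adjusted p = 0.123). The count of 628 ranges from 134 without the fasting control library of 2 h to 1710 without that of 1 h, and without scaling 365 were higher and 808 lower.

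The second insulin experiment, in control cells of the cultures labelled HuR KO or control, gave 1006 higher and 674 lower genes. Angptl8 (2.72 ± 0.22) and Ppp1r3b (1.90 ± 0.21) again stood among the genes that rose most, with the signalling brake Spry4 (1.91 ± 0.12), Fam110c (1.82 ± 0.13) and the isoprenoid enzyme Idi1 (1.71 ± 0.23). Depp1 (−3.28 ± 0.29), Pdk4 (−2.16 ± 0.22), Bmf (−1.92 ± 0.14), Fbxo32 (−1.63 ± 0.22), Txnip (−1.54 ± 0.11) and the death gene Bbc3 (−1.54 ± 0.20) fell most. Of cholesterol synthesis genes 14 of 25 measured rose (17 over the list alone, adjusted p = 0.403 with an estimated correlation), of ribosome biogenesis factors 14 of 35 measured rose (30 over the list alone, adjusted p = 0.406 with an estimated correlation), and of FOXO targets 0 of 24 measured rose and 12 fell (2 and 17 over the list alone, adjusted p = 0.403 with an estimated correlation). Of interferon-stimulated genes 11 of 26 measured rose (21 over the list alone, adjusted p = 0.403 with an estimated correlation), with Isg15 (1.18 ± 0.15). Of macrophage markers 9 of 15 measured fell (12 over the list alone, adjusted p = 0.403 with an estimated correlation), with Lyz2 (−0.67 ± 0.09). Of TFEB genes 9 of 32 measured fell (16 over the list alone, adjusted p = 0.403 with an estimated correlation). Elavl1 (0.36 ± 0.08) rose. The count of 1680 ranges from 35 without the 2 h libraries to 1827, and is 268 from the 6 libraries of these arms alone. The insulin experiments share no library: of the genes called in the first, 93.4% had the same sign in the second, and of those called in the second 93.7% in the first (73.6% of all genes). Both called 180 genes higher (22.1 for independent lists), 110 lower (11.5) and 0 in opposite directions.

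Torin in the control cells of the labelled HuR KO experiment raised 2210 genes and lowered 2201 (2355 and 1515 without scaling). The antagonist of bone morphogenetic proteins Grem1 (3.33 ± 0.25), the bradykinin receptor Bdkrb2 (3.29 ± 0.32), Rgs1 (3.22 ± 0.20), Clec7a (3.05 ± 0.34), the chemokine Cxcl2 (3.00 ± 0.33) and Fgf23 (2.66 ± 0.23) rose most. Ccl12 (−2.57 ± 0.53), Cd248 (−2.53 ± 0.48), the elastic fibre genes Eln (−2.18 ± 0.45) and Mfap2 (−2.15 ± 0.45), Coro1a (−2.07 ± 0.36) and Tmem119 (−2.04 ± 0.42) fell most. Of immediate early genes 21 of 32 measured rose (21 over the list alone, adjusted p = 0.258 with an estimated correlation), of FOXO targets 13 of 23 measured rose and 1 fell (14 and 2 over the list alone, adjusted p = 0.0899 with an estimated correlation), and of inflammatory NF-kB targets 12 of 23 measured rose and 0 fell (13 and 1 over the list alone, adjusted p = 0.245 with an estimated correlation). Of amino acid response genes 5 of 38 measured rose and 21 fell (7 and 24 over the list alone, adjusted p = 0.825 with an estimated correlation). Of cholesterol synthesis genes 15 of 25 measured fell (18 over the list alone, adjusted p = 0.825 with an estimated correlation), and of endoplasmic reticulum chaperones 1 of 19 measured rose and 14 fell (1 and 16 over the list alone, adjusted p = 0.825 with an estimated correlation). Of glycolysis genes 3 of 19 measured rose and 7 fell (3 and 7 over the list alone, adjusted p = 0.97 with an estimated correlation), with Slc16a3 (−1.88 ± 0.17). Elavl1 was at −0.01 ± 0.14 (adjusted p = 0.967). The count of 4411 ranges from 261 without the 6 h libraries to 3866. Against the nutrient experiment, which shares no library with it, 516 genes were higher in both (100 for independent lists), 632 lower in both (141) and 4 opposite (239).

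In the insulin cultures, cells labelled HuR KO had 997 genes higher and 938 lower than control cells, over 6 time-matched pairs. Interferon-stimulated genes stood out: 23 of 26 measured rose (25 over the list alone, adjusted p = 0.339 with an estimated correlation). The rise lay mostly in medium, where their median difference was 0.92 (0.80 to 1.08 over the 3 pairs), against 0.14 (−0.22 to 0.32) with insulin. The chemokine Cxcl10 (1.19 ± 0.15) rose most, with Ifit3b (1.04 ± 0.17), Ifit1 (0.96 ± 0.21) and Ifit3 (0.93 ± 0.19) higher in 5 of 6 pairs each, Crispld2 (0.94 ± 0.08) and Septin11 (0.89 ± 0.05). Of inflammatory NF-kB targets 13 of 21 measured rose and 1 fell (17 and 2 over the list alone, adjusted p = 0.339 with an estimated correlation), with the monocyte chemokine Ccl2 (0.85 ± 0.08). The genes that fell most are Cyp2e1 (−1.68 ± 0.12), the glyceroneogenic enzyme Pck1 (−1.66 ± 0.14), Prl2c3 (−1.46 ± 0.14), Ldoc1 (−1.36 ± 0.10), Rn7sk (−1.33 ± 0.23) and Rnase2b (−1.26 ± 0.24). Of fatty acid oxidation genes 1 of 30 measured rose and 13 fell (1 and 19 over the list alone, adjusted p = 0.536 with an estimated correlation), with the carnitine carrier Slc25a20 (−0.58 ± 0.09), Acaa1b (−0.64 ± 0.10) and Hadha (−0.44 ± 0.08). Of markers of fibroblasts and progenitors 7 of 16 measured rose and 1 fell (11 and 1 over the list alone, adjusted p = 0.585 with an estimated correlation). Of adipocyte identity genes 1 of 19 measured fell (1 over the list alone, adjusted p = 0.665 with an estimated correlation), and of triglyceride genes 3 of 21 measured fell (4 over the list alone, adjusted p = 0.665 with an estimated correlation). Genes of the fixed list were at −0.03 ± 0.12 (Insig1), −0.17 ± 0.08 (Pnpla2, the triglyceride lipase), −0.07 ± 0.09 (Adipoq) and −0.15 ± 0.09 (Pparg). The count of 1935 ranges from 84 without the 2 h libraries to 2834.

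No gene passed the test of a response to insulin that differs by label: limma called 0 genes for the interaction, with 1505 at an unadjusted p under 0.05. As a list, interferon-stimulated genes had a median of −0.89 (22 of 26 lower over the list alone, 0 over all genes, adjusted p = 0.254 with an estimated correlation). Macrophage markers had a median of 0.69 (12 of 15 higher over the list alone, 0 over all genes, adjusted p = 0.254 with an estimated correlation).

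In the Torin cultures, cells labelled HuR KO had 41 genes higher and 133 lower. The matrix protease Mmp9 (1.26 ± 0.24), the kinase Stk38 (0.91 ± 0.13), Apoc3 (0.85 ± 0.14), the sorting receptor Sorl1 (0.84 ± 0.12), Sugct (0.77 ± 0.09) and Ifi27l2a (0.72 ± 0.12) rose most. Prl2c3 (−2.27 ± 0.15), the steroid dehydrogenase Hsd3b6 (−2.18 ± 0.25), Prl2c2 (−1.39 ± 0.19), Gdpd2 (−1.37 ± 0.15), H3c8 (−1.29 ± 0.22) and Car4 (−1.19 ± 0.13) fell most. Of de novo lipogenesis genes 2 of 21 measured rose and 0 fell (7 and 1 over the list alone, adjusted p = 0.522 with an estimated correlation), with Acly (0.63 ± 0.11) and Me1 (0.52 ± 0.09). The acylglycerol enzyme Gpam (0.40 ± 0.06) rose, and Saa3 (−0.69 ± 0.10) and the gelatinase Mmp2 (−0.63 ± 0.07) fell. Of macrophage markers 0 of 15 measured rose (6 over the list alone, adjusted p = 0.522 with an estimated correlation). The count of 174 ranges from 0 without the 3 h libraries to 192. For the interaction with Torin limma called 0 genes, with 276 at an unadjusted p under 0.05. The labelled HuR KO cultures share no library between experiments: 16 genes were higher in both (2.43 for independent lists), 78 lower in both (8.1) and 0 opposite, and 147 of the 163 Torin-experiment genes that could be compared had the same sign in the insulin experiment (63.8% of all genes).

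**Figure D2:**
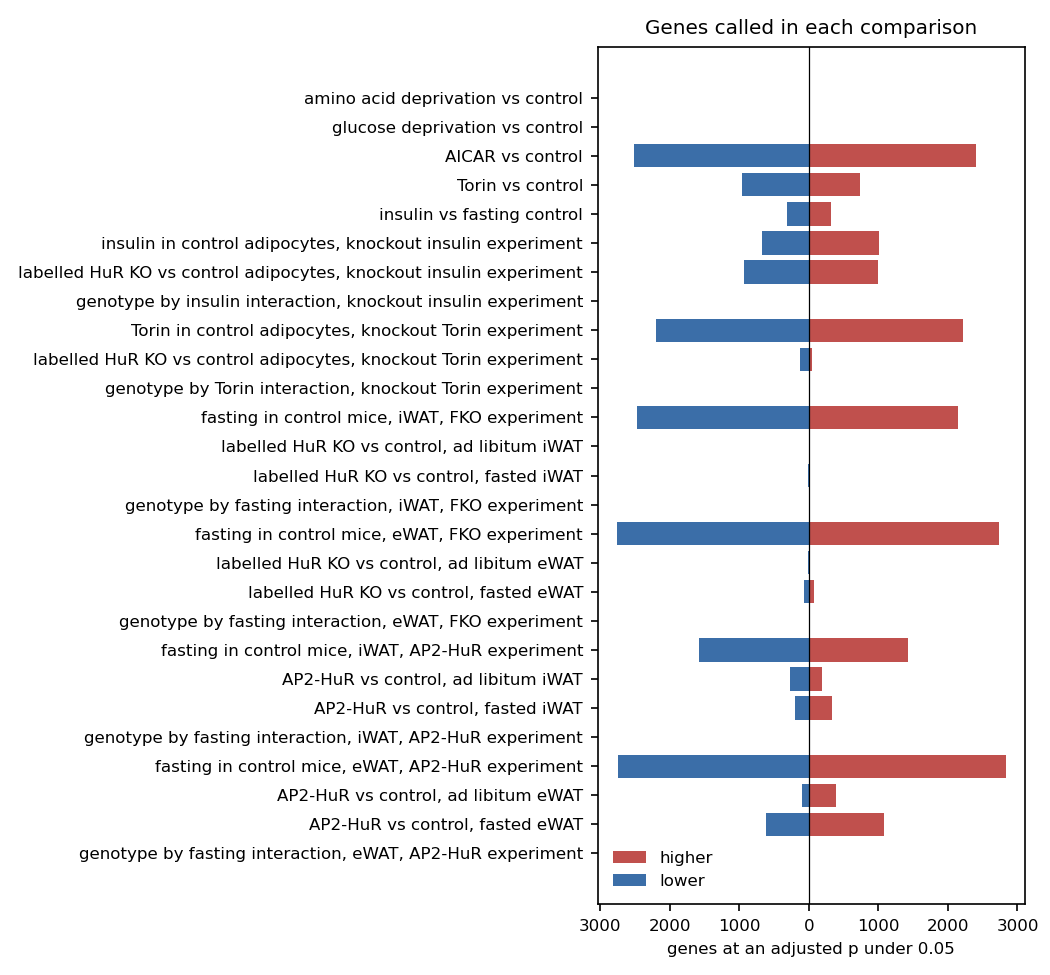
Genes called at an adjusted p under 0.05 in each of the 27 comparisons, higher to the right and lower to the left (bars from 0, linear axis, number of genes). Fasting reaches 5573 calls, and the labelled HuR KO comparisons in tissue reach 151 at most.

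Fasting in the controls of the HuR KO experiment changed 2149 genes upward and 2472 downward in iWAT. Among the genes that rose most are the pantetheinase Vnn1 (3.97 ± 0.39), the imprinted genes Peg3 (3.53 ± 0.27) and Mest (2.86 ± 0.48), Inmt (3.04 ± 0.62) and Cbs (2.85 ± 0.29). The B-cell gene Cd79a (−4.71 ± 0.23), Iglc3 (−4.64 ± 0.34), Ltb (−4.61 ± 0.32), Ly6d (−4.46 ± 0.37), the T-cell factor Tcf7 (−4.25 ± 0.31) and Ppp1r3b (−4.32 ± 0.44) fell most. Of de novo lipogenesis genes 18 of 21 measured fell (18 over the list alone, adjusted p = 0.294 with an estimated correlation), with Fasn (−3.68 ± 0.24) and Scd1 (−0.88 ± 0.25). Of cholesterol synthesis genes 20 of 23 measured fell (20 over the list alone, adjusted p = 0.294 with an estimated correlation). Of B-cell markers 6 of 6 measured fell (6 over the list alone, adjusted p = 0.294 with an estimated correlation), and of T-cell markers 6 of 6 measured fell (6 over the list alone, adjusted p = 0.38 with an estimated correlation). Of endothelial markers 12 of 15 measured rose (13 over the list alone, adjusted p = 0.479 with an estimated correlation), and of erythroid genes 5 of 5 measured rose (5 over the list alone, adjusted p = 0.479 with an estimated correlation). Of oxidative phosphorylation subunits 19 of 48 measured fell (25 over the list alone, adjusted p = 0.706 with an estimated correlation). Lep (−1.59 ± 0.32), the satiety hormone, fell.

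In eWAT of these mice 2738 genes rose and 2758 fell with fasting (1639 and 3304 without scaling). Apoc3 (3.62 ± 0.27), Vnn1 (3.52 ± 0.35), Peg3 (3.42 ± 0.42), the translation brake Eif4ebp3 (3.33 ± 0.31), Thbs1 (3.10 ± 0.35) and Irf4 (3.03 ± 0.53) rose most. Pnpla3 (−4.75 ± 0.25), Fasn (−4.08 ± 0.31), Thrsp (−3.95 ± 0.21), Scd2 (−3.29 ± 0.33), Lep (−3.23 ± 0.24) and Cldn22 (−3.16 ± 0.23) fell most. Of de novo lipogenesis genes 1 of 21 measured rose and 15 fell (2 and 15 over the list alone, adjusted p = 0.677 with an estimated correlation). Of cytosolic ribosomal proteins 35 of 48 measured rose (37 over the list alone, adjusted p = 0.677 with an estimated correlation), and of oxidative phosphorylation subunits 33 of 48 measured fell (37 over the list alone, adjusted p = 0.677 with an estimated correlation). Of clock genes 3 of 17 measured rose and 10 fell (3 and 10 over the list alone, adjusted p = 0.677 with an estimated correlation), with Dbp (−2.79 ± 0.18). Of macrophage markers 8 of 18 measured rose (8 over the list alone, adjusted p = 0.713 with an estimated correlation). Pdk4 (2.58 ± 0.48), Angptl4 (1.24 ± 0.30) and the triglyceride lipase Pnpla2 (1.10 ± 0.20) rose. Elavl1 was at −0.19 ± 0.07 (adjusted p = 0.0649), and in iWAT at −0.33 ± 0.12 (adjusted p = 0.0545).

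Fasting in the controls of the AP2-HuR experiment, 6 libraries per state, raised 1433 genes and lowered 1584 in iWAT (2109 and 1082 without scaling). The imprinted genes Zim1 (2.91 ± 0.25) and Peg3 (2.36 ± 0.21), the mTOR brake Ddit4 (2.67 ± 0.19), Mrgprg (1.98 ± 0.40), the cycle inhibitor Cdkn1a (1.96 ± 0.33) and Inmt (1.95 ± 0.23) rose most. Cdsn (−2.44 ± 0.28), the citrate lyase Acly (−2.44 ± 0.33), Pnpla3 (−2.38 ± 0.21), Odf3l1 (−2.33 ± 0.38), Ppp1r3b (−2.16 ± 0.62) and Angptl8 (−2.14 ± 0.65) fell most. Of glucocorticoid-induced genes 14 of 17 measured rose (14 over the list alone, adjusted p = 0.0149 with an estimated correlation), a call that held, and of de novo lipogenesis genes 0 of 21 measured rose and 15 fell (1 and 17 over the list alone, adjusted p = 0.113 with an estimated correlation). Replicates 1 to 3 gave 1952 and 1935, 4 to 6 gave 2005 and 1618, where fasting coincides with a difference between libraries described below. In eWAT 2829 genes rose and 2744 fell. Irf4 (3.35 ± 0.34), Zim1 (3.17 ± 0.40), Apoc3 (3.05 ± 0.57), Ddit4 (2.66 ± 0.16), Pdk4 (2.27 ± 0.39) and Peg3 (2.26 ± 0.28) rose most, and Pnpla3 (−3.30 ± 0.28), Fasn (−2.76 ± 0.35), Igfals (−2.69 ± 0.28), Cdsn (−2.56 ± 0.30), Lep (−2.49 ± 0.29) and Fam83a (−2.38 ± 0.27) fell most. Of de novo lipogenesis genes 1 of 21 measured rose and 17 fell (1 and 18 over the list alone, adjusted p = 0.00611 with an estimated correlation), which held too. Of ribosomal proteins 38 of 48 measured rose (38 over the list alone, adjusted p = 0.224 with an estimated correlation), and of glycolysis genes 1 of 19 measured rose and 13 fell (1 and 13 over the list alone, adjusted p = 0.19 with an estimated correlation). Replicates 1 to 3 gave 2505 and 2780 in eWAT, 4 to 6 gave 3074 and 3001.

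The fasted AP2-HuR experiment libraries numbered 4 to 6 stand apart from those numbered 1 to 3, in both genotypes and both depots. Between these sets 5655 genes differed in fasted iWAT and 5857 in fasted eWAT, against 3438 and 3446 in the ad libitum state. Genes whose exons lie almost wholly under exons of the other strand, whatever the level there, were higher in fasted libraries 4 to 6. Their median log2 difference was 1.68 in iWAT (111 of 123 genes higher) and 1.07 in eWAT (126 of 142 genes). In ad libitum libraries that difference was −0.11 and −0.06, and over all genes it was within 0.02. The count of genes called between AP2-HuR and control mice therefore stands beside its values within replicates 1 to 3 and 4 to 6. The fasting experiments share no library: their calls went in opposite directions for 175 genes in iWAT (483 for independent lists) and 161 in eWAT (1040).

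Between tissues labelled HuR KO and control, few genes passed. In ad libitum iWAT 3 did, the zinc finger gene Zfp949 (1.47 ± 0.13) and the kinase Stk38 (0.96 ± 0.12) upward and A430018G15Rik (−1.70 ± 0.19) downward (5 up and 8 down without scaling). Cell cycle genes were higher as a list (13 of 22 over the list alone, 0 over all genes, adjusted p = 0.245 with an estimated correlation). So were B-cell markers (6 of 6 over the list alone, 0 over all genes, adjusted p = 0.245 with an estimated correlation). Limma on these 6 libraries alone called 0 (531 at an unadjusted p under 0.05). With the replicate block only Zfp949 still passed (1.47 ± 0.09), while Stk38 (0.96 ± 0.12) and A430018G15Rik (−1.70 ± 0.20) did not. Mitochondrial transcripts were high in both replicate 1 libraries, and 1 of the other splits, which sets control 1 with labelled HuR KO 1 and 2, called 2106 genes. In fasted iWAT 16 genes rose and 9 fell (4 and 10 without scaling). Krt79 (1.84 ± 0.29), the granzyme Gzmb (1.5 ± 0.24), Aldh3b2 (1.45 ± 0.20), the glutathione transferase Gsta4 (1.32 ± 0.17), Hist1h4h (1.23 ± 0.18) and the transporter Slc16a12 (1.09 ± 0.16) rose most, and Sh2d4a (−0.61 ± 0.10) was among those that fell. Leaving out any 1 of these 6 libraries left 0 or 1 calls, and the 6 alone gave 43.

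In ad libitum eWAT, tissues labelled HuR KO had 19 genes higher and 13 lower. The muscle methyltransferase Smyd1 (1.72 ± 0.28), Stk38 (1.41 ± 0.11), Zfp949 (1.38 ± 0.11), Hist1h4h (1.23 ± 0.11), Gsta4 (0.97 ± 0.16) and AC164550.2 (0.86 ± 0.13) rose most. Dlst (−0.97 ± 0.08), a subunit of the oxoglutarate dehydrogenase complex, the importin Tnpo2 (−0.87 ± 0.07), Svip (−0.87 ± 0.09), the cortisone reductase Hsd11b1 (−0.79 ± 0.13), Tmem250-ps (−0.77 ± 0.07) and Apoe (−0.67 ± 0.10) fell most. Leaving out any 1 of these libraries gives 10 to 36 calls, and limma on these 6 libraries alone calls 0 (797 at an unadjusted p under 0.05). In fasted eWAT 80 genes rose and 71 fell (22 and 50 without scaling). Smyd1 (1.71 ± 0.28), the synaptic protein Clstn3 (1.57 ± 0.32), Krt79 (1.45 ± 0.23), the oxytocin receptor Oxtr (1.42 ± 0.29) and Gsta4 (1.26 ± 0.16) rose most, and Ighj3 is listed at 0 TPM in all 3 controls. Fxyd7 (−1.02 ± 0.16), H2-Q10 (−0.92 ± 0.15), the choline dehydrogenase Chdh (−0.90 ± 0.17), Kiss1r (−0.88 ± 0.16), Ttc36 (−0.84 ± 0.17) and Neil2 (−0.84 ± 0.16) fell most. Of adipocyte identity genes 2 of 20 measured rose (6 over the list alone, adjusted p = 0.218 with an estimated correlation), and of triglyceride genes 1 of 21 measured rose (4 over the list alone, adjusted p = 0.218 with an estimated correlation).

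The adipocyte genes of the fixed list in fasted eWAT were at 0.15 ± 0.20 (Pnpla2, adjusted p = 0.801), 0.00 ± 0.18 (Insig1, adjusted p = 0.998), 0.10 ± 0.14 (Adipoq, adjusted p = 0.81) and 0.37 ± 0.16 (Pparg, adjusted p = 0.322). Without any 1 of the 6 libraries the fasted eWAT count of 151 becomes 15 to 95, and from these 6 alone 310. For the interaction of label and fasting limma called 0 genes in iWAT (527 at an unadjusted p under 0.05) and 0 in eWAT (631). Over the 6 comparisons of a labelled HuR KO group with its controls, cultures and tissues together, 2144 genes were called in at least 1. Of these, 20 were called in the same direction in at least 3, and 9 in at least 4. A430018G15Rik fell in all 6 and Stk38 rose in 5, in fits without the replicate block, with which neither passed in ad libitum iWAT. Dlst, Hsd11b1 and Tnpo2 fell in 4, and Slc18b1 rose in 4. Of 26 genes called in ad libitum eWAT that could be compared, 25 had the same sign in the insulin cultures (96.2%) and 24 in the Torin cultures (92.3%), with 0 opposite calls. For fasted eWAT these were 93 of 133 (69.9%, 2 opposite calls) and 99 of 132 (75%, 0), and for fasted iWAT 11 of 15 (73.3%) and 14 of 17 (82.4%). Over all genes the shares in these comparisons were 51.3% to 57.5%.

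**Figure D3:**
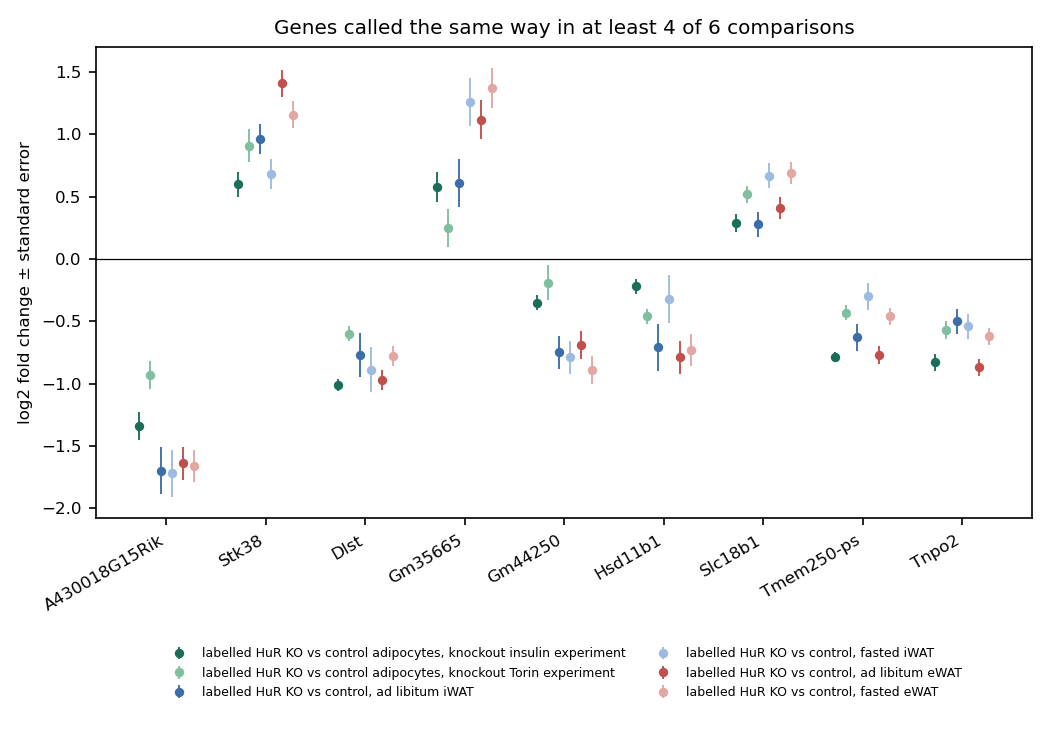
Log2 fold change (labelled HuR KO minus control, ± standard error) of the genes called in the same direction in at least 4 of 6 comparisons, 1 point per comparison. A430018G15Rik lies below 0 in all 6 and Stk38 above 0 in all 6.

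AP2-HuR iWAT in the ad libitum state had 195 genes higher and 270 lower than its controls (137 and 111 without scaling). Apart from Elavl1, the stress hormone Gdf15 (2.65 ± 0.34) and the cell cycle and p53 pathway genes Gtse1 (2.02 ± 0.23) and Cdkn1a (1.55 ± 0.33) rose most, with the imprinted RNA H19 (1.84 ± 0.48) and the carboxylesterase Ces2e (1.5 ± 0.24). Rnu73b (−1.19 ± 0.32), Slc26a10 (−1.19 ± 0.28), Apol10b (−1.15 ± 0.16), Coro6 (−1.15 ± 0.27), the cadherin Celsr2 (−1.07 ± 0.29) and St6galnac5 (−1 ± 0.24) fell most. Of adipocyte identity genes 1 of 20 measured fell (2 over the list alone, adjusted p = 0.46 with an estimated correlation), and of Schwann-cell markers 1 of 9 measured rose (6 over the list alone, adjusted p = 0.433 with an estimated correlation). Fibroblast and progenitor markers (2 of 16 rose, 4 over the list alone), matrix genes (1 of 26, 3), cell cycle genes (1 of 26, 9) and cytosolic ribosomal proteins (1 of 47, 17) were higher as lists, each at an adjusted p = 0.46 with an estimated correlation. With the replicate block 4 adipocyte genes fell over the list alone, and 13 matrix and 14 cell cycle genes rose. Fitted apart, replicates 1 to 3 gave 120 and 54, and 4 to 6 gave 314 and 648. Leaving out 1 library gives 191 (AP2-HuR library 5) to 567 calls for 465. In fasted iWAT 334 genes rose and 196 fell (351 and 129 without scaling). Gdf15 (3.6 ± 0.34), Gtse1 (2.84 ± 0.23) and Ces2e (2.69 ± 0.24) rose most beside Elavl1, with the muscle genes Pygm (2.64 ± 0.75) and Myl1 (2.18 ± 0.52) higher in 5 of 6 same-numbered pairs each. With the replicate block Pygm (2.64 ± 0.81) no longer passed. Ighj2 (−1.48 ± 0.39), St6galnac5 (−1.21 ± 0.24), Slc26a10 (−1.06 ± 0.28), Celsr2 (−1.03 ± 0.29), Timp4 (−0.96 ± 0.15) and the chemerin receptor Cmklr1 (−0.89 ± 0.17) fell most.

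Of Schwann-cell and nerve markers in fasted AP2-HuR iWAT, 8 of 9 measured rose (8 over the list alone, adjusted p = 0.0256 with an estimated correlation). With the replicate block that list missed the threshold at an adjusted p of 0.0534. Of skeletal muscle genes 1 of 14 measured rose (13 over the list alone, adjusted p = 0.461 with an estimated correlation), and of adipocyte identity genes 2 of 20 measured fell (9 over the list alone, adjusted p = 0.435 with an estimated correlation). Within replicates 1 to 3 the fasted counts were 808 and 534, within 4 to 6 165 and 187. For the interaction in iWAT, 1 gene passed, the chitinase-like Chil6 (1.37 ± 0.21), and 827 had an unadjusted p under 0.05. Within replicates 1 to 3 limma called 0, within 4 to 6 237.

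AP2-HuR eWAT in the ad libitum state had 390 genes higher and 101 lower. Gdf15 (3.25 ± 0.37), Gtse1 (2.87 ± 0.26), Cdkn1a (2.16 ± 0.30), Fam167b (1.83 ± 0.17) and the ectodysplasin receptor Eda2r (1.48 ± 0.18) rose most beside Elavl1. Apol10b (−1.22 ± 0.18), Pbld1 (−1.06 ± 0.21), Coro6 (−1.06 ± 0.15), Dusp26 (−1 ± 0.19), Lnx1 (−0.73 ± 0.15) and the carbonic anhydrase Car4 (−0.68 ± 0.16) fell most. Of cell cycle genes 9 of 27 measured rose (19 over the list alone, adjusted p = 0.364 with an estimated correlation), of matrix genes 5 of 26 measured rose (10 over the list alone, adjusted p = 0.149 with an estimated correlation), with the basement membrane collagen Col4a1 (0.63 ± 0.09), and of macrophage markers 3 of 18 measured rose (8 over the list alone, adjusted p = 0.364 with an estimated correlation). Fitted apart, replicates 1 to 3 gave 295 and 25, and 4 to 6 gave 210 and 87. In fasted eWAT 1084 genes rose and 620 fell (1231 and 399 without scaling). Gdf15 (4.46 ± 0.37), Gtse1 (4.41 ± 0.26), Eda2r (2.53 ± 0.18), Zfp365 (2.40 ± 0.19) and Fam167b (2.30 ± 0.17) rose most beside Elavl1. Dusp26 (−1.56 ± 0.19), Igkv14-126 (−1.55 ± 0.43), Pbld1 (−1.42 ± 0.21), Coro6 (−1.39 ± 0.15), Apol10b (−1.13 ± 0.18) and the cycle inhibitor Cdkn1c (−1.06 ± 0.14) fell most.

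In fasted AP2-HuR eWAT, of cell cycle genes 18 of 27 measured rose (20 over the list alone, adjusted p = 0.271 with an estimated correlation), and of matrix genes 9 of 26 measured rose and 0 fell (16 and 1 over the list alone, adjusted p = 0.088 with an estimated correlation). Of endoplasmic reticulum chaperones 9 of 19 measured rose (13 over the list alone, adjusted p = 0.235 with an estimated correlation), of amino acid response genes 10 of 36 measured rose (11 over the list alone, adjusted p = 0.411 with an estimated correlation), and of macrophage markers 9 of 18 measured rose (12 over the list alone, adjusted p = 0.235 with an estimated correlation). Of neutrophil markers 1 of 5 measured rose (4 over the list alone, adjusted p = 0.359 with an estimated correlation), and of adipocyte identity genes 1 of 20 measured fell (1 over the list alone, adjusted p = 0.525 with an estimated correlation), 2 over the list alone with the replicate block. Of the transcripts described as bound by HuR 6 of 25 measured rose (6 over the list alone, adjusted p = 0.088 with an estimated correlation). Within replicates 1 to 3 the counts were 961 and 318, within 4 to 6 518 and 221. For the interaction in eWAT limma called 9 genes, all higher, with 1138 at an unadjusted p under 0.05. Apart from Elavl1 they include the collagen folding enzyme Fkbp14 (0.67 ± 0.08), Tceal9 (0.52 ± 0.08), the GTPase Arf2 (0.42 ± 0.07), the p53 target Ccng1 (0.38 ± 0.07) and the calcium binder Calu (0.32 ± 0.06). Chaperones had a median of 0.26 (11 of 19 higher over the list alone, 0 over all genes, adjusted p = 0.271 with an estimated correlation). Within replicates 1 to 3 limma called 18, within 4 to 6 0.

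**Figure D4:**
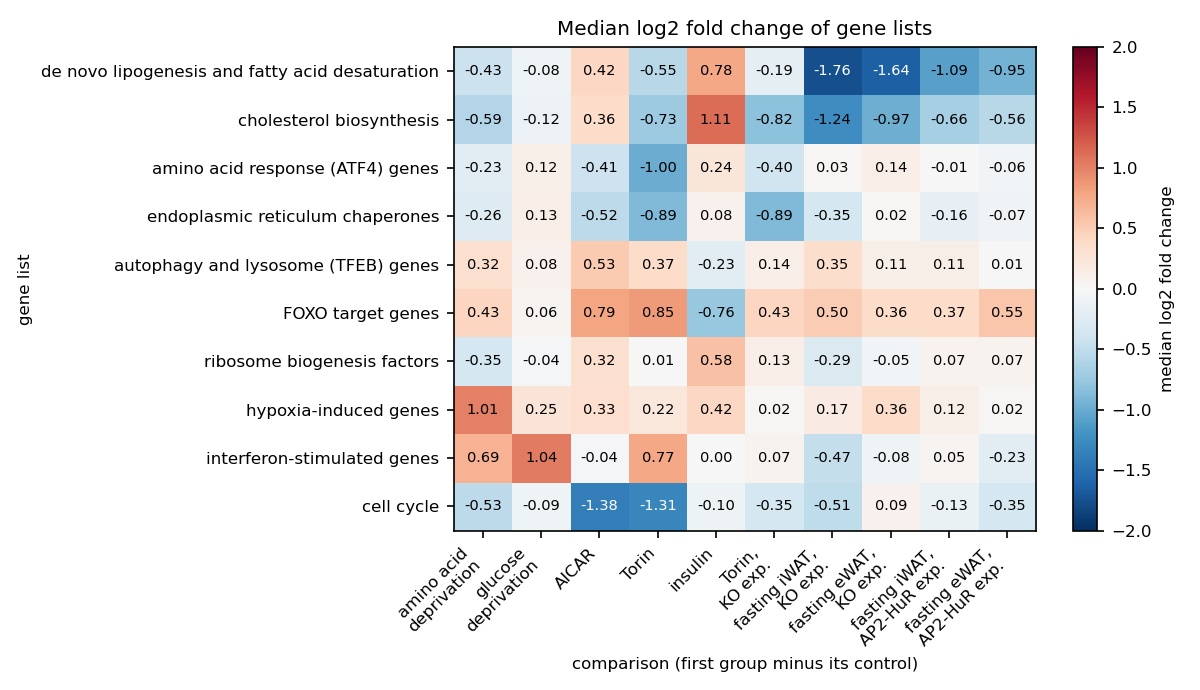
Median log2 fold change of 10 fixed gene lists (rows) in 10 comparisons (columns), as a colour scale with the value in each cell. De novo lipogenesis lies below 0 in all fasting comparisons, and interferon-stimulated genes reach 1.04 with glucose deprivation.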

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

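The tests of exchanged labels, scaling, B cells, lymph node, antisense reads and pseudogenes were chosen after the results were seen, and those of proportional antisense reads and of depth before.

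Elavl1 was not lower in cultures labelled HuR KO. If the labels had been exchanged, with a deletion that strongly lowers the mRNA, control cells would hold less than cells labelled HuR KO by a log2 difference of 1 or more. The highest difference of both experiments was 0.25, with standard errors of 0.06 and 0.10, which argues against that. Scaling does not account for it either, since over 3 scalings the lowest difference was 0.15. A deletion that leaves most reads of the gene in place, and unaltered cells under the label, stay open, and gene-level values cannot tell them apart.

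B-cell markers fell in iWAT of fasted mice of the HuR KO experiment, under both labels: the median log2(TPM + 1) was 6.4 to 7.8 in the ad libitum libraries and 2.58 to 2.86 in the fasted ones. A loss of B cells from fat on fasting in general would lower them in the other 3 fasting comparisons too, where the highest median change was 0.49. Lymph node tissue in the ad libitum samples would bring genes of lymph node structure, of which 3 of 11 listed are measured: Ccl21a fell (−2.64 ± 0.39, 22.4 TPM fasted against 163 TPM), while Cxcl13 was at 1.06 ± 0.38 (266 against 140 TPM) and Mfge8 rose (0.89 ± 0.11, 288 against 154 TPM). With members moving both ways their median of 0.89 decides nothing, so lymph node tissue stays open. A change of B cells in this depot and experiment alone stays open as well, and was not tested.

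The fasted libraries of the AP2-HuR experiment numbered 4 to 6 lie apart from numbers 1 to 3. Reads of the opposite strand counted in these libraries would raise genes lying under exons of the other strand. The lower of both depots' median differences for such genes was 1.07, against −0.11 and −0.06 in the ad libitum state. The rise followed the ratio of the other strand's genes with rank correlations of 0.53 in iWAT and 0.45 in eWAT across genes, which are not independent replicates, so proportional reads are not settled. All 12 libraries also have an estimated depth below that of the others (in M reads, 50.5 to 57.1 in iWAT and 54.1 to 59.7 in eWAT, against 62.9 to 77.8 and 63 to 79), so strand and depth cannot be told apart as marks of a batch. Processed pseudogenes were lower in these libraries than in numbers 1 to 3, by a median of −0.60 in iWAT (279 of 492 called) and −0.68 in eWAT (287 of 499), against 0.11 and 0.13 in the ad libitum state. The labels name no batch, and no biological explanation was tested.

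Of 145 gene and group pairs in AP2-HuR tissues with 6 libraries, 10 held a library far from the others, and chance would give about 1 in 20, or 7.25. The value is the gap to the nearest library over the range of the group. In fasted iWAT they were Ces2e in AP2-HuR library 6 (0.819, 34.8 TPM against 7.92 to 12.8), Gtse1 in AP2-HuR library 6 (0.655, 9.15 TPM), Ces2e in control library 6 (0.693, 0.472 TPM), and the muscle genes Myl1 (0.721, 96.2 TPM against 28.9 to 47.7) and Pygm (0.821, 54.4 TPM against 10.3 to 18.2) in control library 6. In ad libitum iWAT it was Angptl8 in control library 6 (0.729, 241 TPM against 16.8 to 77.4). In ad libitum eWAT they were Cdkn1a (0.773, 23.1 TPM) and Apoc3 (0.745, 24.5 TPM) in control library 6 and Gdf15 in control library 1 (0.722, 1.97 TPM). In fasted eWAT it was Fam167b in AP2-HuR library 3 (0.630, 15.1 TPM against 19.5 to 22.1).

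The effect of fasting differed between AP2-HuR and control mice, by the test of the interaction, for 10 genes. In iWAT this was Chil6 (1.37). In eWAT these were Elavl1 (1.20), Fkbp14 (0.67), Tceal9 (0.52), Arf2 (0.42), Ccng1 (0.38) and Calu (0.32), and, named after their values were seen, Mybl1 (1.16), Bean1 (1.00) and Gm48783 (1.33). Of 115 genes compared between depots, 4 moved in opposite directions in every library, a difference that was not tested. In ad libitum tissue labelled HuR KO, Smyd1 averaged 2.94 TPM against 6.37 TPM in iWAT and 11 TPM against 2.51 TPM in eWAT. With fasting in controls of the HuR KO experiment, Cd79a averaged 4.36 against 141 TPM in iWAT and 8.01 against 4.57 TPM in eWAT. Ly6d averaged 3.12 against 88.5 and 5.03 against 2.71 TPM there, and Tcf7 2.69 against 75.5 and 6 against 3.35 TPM.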

How the results depend on the processing

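Chosen after seeing the data were the fits without scaling, with pseudocounts of 0.25 and 4, without doubted libraries, within replicates 1 to 3 and 4 to 6 of the AP2-HuR experiment and with a term for its fasted libraries numbered 4 to 6. All others were fixed before the data were examined, and where a value moved the cause was not tested. Tests with DESeq2, fixed as well, were not run, because the values are not counts. Over 297 printed gene results and 5734 refits of them, 5058 kept direction and side of the threshold, 649 fell short of it, 27 passed it newly and 0 turned. With RLE factors all 297 kept their side of it. Having no filter on low values tests little, since the deposited genes were filtered already. A replicate block moved no other count by over 1.5 times than the 2 named below and ended the calls of 15 of 154 gene results. Where numbers were taken to pair the libraries, it changed no list call given in the text but that of Schwann-cell markers.

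Counts that moved by over 1.5 times are given as totals, the designed fit's first. With only the groups compared, totals became, for amino acid deprivation 0 to 265, AICAR 4919 to 2089, Torin 1690 to 5, insulin in the second experiment 1680 to 268, Torin in the second 4411 to 2645, fasting in iWAT of the HuR KO experiment 4621 to 3037, labelled HuR KO 3 to 0 (ad libitum iWAT), 25 to 43 (fasted iWAT), 32 to 0 (ad libitum eWAT) and 151 to 310 (fasted eWAT), AP2-HuR 465 to 1083 (ad libitum iWAT) and 530 to 200 (fasted iWAT). With no time term they were, for AICAR 3186, Torin 404, insulin 75, second insulin 977, second Torin 2160 and labelled HuR KO in the Torin cultures 39. As deposited, with no scaling, they were, for amino acid deprivation 1, AICAR 2775, Torin 595, insulin 1173, labelled HuR KO 13 (ad libitum iWAT), 14 (fasted iWAT) and 72 (fasted eWAT), and AP2-HuR ad libitum iWAT 248. That setting shifts the median of all genes by −0.19 for glucose deprivation, −0.135 for AICAR and −0.105 for Torin.

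With a mean of at least 4 TPM they were, for labelled HuR KO fasted iWAT 11, ad libitum eWAT 21, label by insulin 7, AP2-HuR interaction in iWAT 0. With a replicate block they were, for labelled HuR KO ad libitum iWAT 1, ad libitum eWAT 12. With a pseudocount of 0.25 the AP2-HuR interaction in iWAT was 0, and with 4 that in eWAT 15. Both experiments in 1 fit gave 2995 for insulin and 4786 for Torin, and Torin without the libraries rich in Gm23935 gave 240. Replicates 1 to 3, then 4 to 6, then all with the term gave 174, 962 and 1114 for AP2-HuR ad libitum iWAT, 1342, 352 and 888 for fasted iWAT, 0, 237 and 1 for its interaction, 320, 297 and 829 for ad libitum eWAT, 1279, 739 and 2500 for fasted eWAT, 18, 0 and 20 for its interaction, and with the term 4565 for fasting in iWAT. Of 900 list tests 311 passed with the preset correlation and 4 with an estimated one. Between labelled HuR KO and AP2-HuR fasted eWAT the same-sign share of 53.1% became 38.5% with calls at an adjusted p under 0.01.

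Leaving out 1 library or time, where an arm with 1 library left is assumed to vary like the others, moved these totals by over 1.5 times (KO stands for labelled HuR KO, fed for ad libitum). AICAR gave 928 without the 6 h libraries, 1844 without the 12 h libraries, 2599 without control 6 h, 2776 without AICAR 6 h, highest 5785. Torin gave 0 without the 6 h libraries, 1 without the 12 h libraries, 92 without control 6 h, 140 without Torin 6 h, 418 without control 12 h, 596 without Torin 12 h, 931 without control 3 h, highest 1621. Insulin gave 134 without fasting control 2 h, 235 without the 2 h libraries, 252 without insulin 2 h, 1015 without insulin 1 h, 1094 without the 1 h libraries, 1710 without fasting control 1 h. Second insulin gave 35 without the 2 h libraries, 332 without control insulin 2 h, 372 without control medium 2 h, 582 without the 4 h libraries, 594 without control medium 4 h, 737 without control insulin 4 h, highest 1827. Labelled HuR KO in insulin cultures gave 84 without the 2 h libraries, 303 without the 1 h libraries, 1023 without control insulin 2 h, 1035 without KO insulin 2 h, 1049 without KO medium 4 h, 1070 without control medium 2 h, 1107 without KO medium 2 h, 1199 without control insulin 1 h, 1239 without KO medium 1 h, 1249 without KO insulin 1 h, highest 2834. Its interaction gave 2 without control insulin 4 h, lowest 0. Second Torin gave 261 without the 6 h libraries, 2220 without control Torin 12 h, 2319 without control DMSO 12 h, 2352 without control DMSO 6 h, 2389 without the 12 h libraries, highest 3866. Labelled HuR KO in Torin cultures gave 0 without the 3 h libraries, 1 without the 6 h libraries, 34 without the 12 h libraries, 37 without KO DMSO 6 h, 52 without control DMSO 6 h, 57 without control Torin 6 h, 63 without control DMSO 12 h, 64 without KO Torin 6 h, 67 without control Torin 3 h, 100 without control DMSO 3 h, highest 192. KO in ad libitum iWAT gave 1 without control fed 3 or KO fed 1, 2 or 3, highest 4. Fasted iWAT gave 0 without control fasted 1, 2 or 3 or KO fasted 2 or 3, and 1 without KO fasted 1. Ad libitum eWAT gave 10 without KO fed 1, 13 without KO fed 3, 19 without KO fed 2, highest 36. Fasted eWAT gave 15 without control fasted 2, 19 without control fasted 3, 22 without KO fasted 2, 27 without KO fasted 1, 82 without control fasted 1, 95 without KO fasted 3. AP2-HuR ad libitum iWAT gave 191 without AP2-HuR fed 5, 202 without AP2-HuR fed 4, 209 without control fed 3, 210 without control fed 2, 253 without control fed 6, 270 without control fed 4, highest 567. Interaction in iWAT gave 0 without AP2-HuR fed 6, control fed 2, 3, 5 or 6, or AP2-HuR fasted 2, 3, 4 or 5. It also gave 0 without control fasted 1, 3, 4 or 6, and 2 without AP2-HuR fed 2, 3 or 4. Interaction in eWAT gave 5 without AP2-HuR fed 3, control fed 3 or 4, AP2-HuR fasted 1 or control fasted 3. It gave 17 without AP2-HuR fed 6, 20 without AP2-HuR fed 5. Fasting gave 3249 to 4736 in iWAT and 4389 to 5486 in eWAT of the HuR KO experiment, 2379 to 3143 and 4874 to 5437 in the AP2-HuR experiment. AP2-HuR gave 358 to 554 in fasted iWAT, 371 to 487 in ad libitum and 1357 to 1689 in fasted eWAT. Amino acid and glucose deprivation and the other interactions gave 0 throughout. In simulated data of each design a log2 change of 0.5 was recovered for 0% to 71.6% of genes. Depth was not varied there, so its limit was not measured.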

Other observations

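The p53 and position tests below were written before their results were seen, and the neighbours of shared genes and the counts of other splits after.

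Beyond lipid synthesis, fasting in controls of the HuR KO experiment moved further gene groups. In iWAT, of FOXO targets, which insulin holds down, 11 of 23 measured rose and 1 fell (12 and 2 over the list alone, adjusted p = 0.479 with an estimated correlation). Of glucocorticoid-induced genes 9 of 17 measured rose (9 over the list alone, adjusted p = 0.602 with an estimated correlation), and of TFEB genes 12 of 30 measured rose and 1 fell (18 and 1 over the list alone, adjusted p = 0.479 with an estimated correlation). Of ribosome biogenesis factors 1 of 35 measured rose and 16 fell (3 and 19 over the list alone, adjusted p = 0.602 with an estimated correlation), and of cell cycle genes 1 of 22 measured rose and 14 fell (1 and 14 over the list alone, adjusted p = 0.479 with an estimated correlation). Of interferon-stimulated genes 1 of 25 measured rose and 8 fell (1 and 8 over the list alone, adjusted p = 0.706 with an estimated correlation). In the same libraries 6 of 6 B-cell and 6 of 6 T-cell markers fell, and what a change in lymphocytes adds to these falls was not separated. In eWAT, of matrix genes 13 of 26 measured rose and 1 fell (13 and 1 over the list alone, adjusted p = 0.713 with an estimated correlation), while in the AP2-HuR experiment 4 of 26 measured rose and 13 fell (4 and 13 over the list alone, adjusted p = 0.753 with an estimated correlation). There too, of FOXO targets 16 of 23 measured rose and 2 fell (16 and 2 over the list alone, adjusted p = 0.081 with an estimated correlation), of glucocorticoid-induced genes 13 of 17 measured rose (14 over the list alone, adjusted p = 0.121 with an estimated correlation), and of erythroid genes 5 of 5 measured rose (5 over the list alone, adjusted p = 0.482 with an estimated correlation).

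In the cultures, AICAR also moved glucocorticoid-induced genes (9 of 17 measured rose and 1 fell (10 and 1 over the list alone, adjusted p = 0.326 with an estimated correlation)), FOXO targets (11 of 23 measured rose and 2 fell (11 and 2 over the list alone, adjusted p = 0.702 with an estimated correlation)) and oxidative phosphorylation subunits, where 10 of 48 measured rose (0 over the list alone, adjusted p = 0.694 with an estimated correlation). With Torin in wild-type cells, of thermogenic genes 3 of 15 measured rose (6 over the list alone, adjusted p = 0.659 with an estimated correlation), of FOXO targets 9 of 23 measured rose and 2 fell (11 and 3 over the list alone, adjusted p = 0.659 with an estimated correlation), and of matrix genes 10 of 26 measured fell (11 over the list alone, adjusted p = 0.659 with an estimated correlation). Torin in the other cultures gave glucocorticoid-induced genes, 10 of 17 measured rose and 1 fell (10 and 2 over the list alone, adjusted p = 0.245 with an estimated correlation). Insulin in the first experiment gave hypoxia-induced genes, 5 of 19 measured rose and 0 fell (9 and 2 over the list alone, adjusted p = 0.68 with an estimated correlation), and in the second 5 of 19 measured rose and 1 fell (9 and 3 over the list alone, adjusted p = 0.403 with an estimated correlation). In insulin cultures labelled HuR KO, of thermogenic genes 0 of 14 measured rose and 5 fell (1 and 9 over the list alone, adjusted p = 0.649 with an estimated correlation), of oxidative phosphorylation subunits 6 of 48 measured fell (10 over the list alone, adjusted p = 0.665 with an estimated correlation), and of epithelial markers 2 of 4 measured fell (3 over the list alone, adjusted p = 0.339 with an estimated correlation), with Krt8 (−1.10 ± 0.11).

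AP2-HuR tissue held more mRNA of p53 target genes, which was tested as a hypothesis because Cdkn1a, Gdf15 and Gtse1 rose there. Of 25 listed target genes without these 3, 24 are measured. Their median was 0.24 in ad libitum iWAT (0 of them higher over all genes, 8 higher and 1 lower adjusted over the list alone), 0.38 in fasted iWAT (8 higher, 16 and 1), 0.22 in ad libitum eWAT (6 higher and 1 lower, 11 and 2) and 0.43 in fasted eWAT (12 higher, 13 and 1). The test against other genes gave p = 2.89e-05, 5.58e-12, 1.55e-07 and 3.14e-12 in limma, and 0.00776, 9.11e-05, 0.00507 and 4.58e-04 with an estimated correlation. Called genes include Mdm2 and the death genes Bax, Bbc3, Pmaip1 and Apaf1. In tissues labelled HuR KO the medians were 0.02, −0.05, 0.02 and −0.06. The values are consistent with a p53 response in AP2-HuR fat, found and tested on the same mice; what raises these transcripts was not tested.

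The genes that differ between tissues labelled HuR KO and control could have come with the DNA of another strain around or away from Elavl1. Linked DNA as the source would put over 20% of them within 20 Mb of Elavl1. Of 168 called genes with a position 2 lie there, Elavl1 itself, called in fasted eWAT, included. With it that is 1.19% (95% interval 0.144% to 4.23%) against 0.785% of the tested genes (Fisher's exact test, p = 0.381). The other 166 lie elsewhere, which argues against linked DNA for the called set and leaves it open for the gene near Elavl1. With a called neighbour within 5 Mb there were 96, against a median of 97 in 10000 random gene sets of like expression and 108 at their highest 5%. Since 57.7% of a random set has such a neighbour, a few stretches of foreign DNA would not move this count and stay open. Of the 20 genes shared by at least 3 comparisons, Zfp949 (higher) and 9330159M07Rik (lower) start 0.292 Mb apart on chromosome 9, and no others closer than 10.4 Mb. Of genes called for the HuR KO label, the sign in AP2-HuR mice was the same for 1 of 3 in ad libitum iWAT, 6 of 22 in fasted iWAT (27.3%), 8 of 29 in ad libitum eWAT (27.6%) and 76 of 143 in fasted eWAT (53.1%). Of genes called in AP2-HuR mice it was the same under that label for 138 of 430 (32.1%), 152 of 445 (34.2%), 268 of 441 (60.8%) and 955 of 1546 (61.8%). Over all genes the shares were 43.1%, 41.5%, 48.9% and 55.1%.

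Other splits of the same libraries were fitted in the same way, and the highest count of another split stands beside the real one. With 10 splits of 3 against 3 libraries none can reach a share under 0.05. Amino acid and glucose deprivation called 0, as did all 10 splits. The real split was 1 of 10 with as many genes for AICAR (4919, highest other 0), Torin (1690, 0), insulin (628, 1), insulin in the second experiment (1680, 0), Torin in its second experiment (4411, 1), fasting in iWAT and eWAT of the HuR KO experiment (4621, 0 and 5496, 0), and labelled HuR KO in fasted iWAT (25, 1), ad libitum eWAT (32, 1) and fasted eWAT (151, 0). In ad libitum iWAT 2 of 10 splits called as many as the real 3, the other 2106. Its first group holds control 1 with labelled HuR KO 1 and 2, which points to a structure of these libraries, whose replicate 1 pair is rich in mitochondrial transcripts. Of the 4 splits that part same-numbered pairs, 1 called 3 and the others at most 1.

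For labelled HuR KO cultures, of 100 relabellings the real one alone was as high in the insulin (1935, highest other 51) and Torin experiments (174, 1). Of the 32 that part every time-matched pair it was 1 in both (highest others 63 and 0). This cannot exclude chance between cultures. The interactions called 0 genes with insulin, Torin, fasting in iWAT and fasting in eWAT, so that 100 of 100 draws called as many. The highest others were 55, 812, 1261 and 2, and the first 3 of these point to structure in the libraries beyond label and treatment. In the AP2-HuR experiment, 1 of 100 splits was as high for fasting in iWAT (3017, highest other 899) and eWAT (5573, 2647), and 1 of 100 for ad libitum iWAT (465, 4). There, 1 of the 32 splits that part every pair was as high (highest other 3).

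For fasted AP2-HuR iWAT 8 of 100 splits called as many as the real 530, up to 3018 for a split close to numbers 1 to 3 against 4 to 6, so chance is not excluded over all splits. Among the 32 that part every pair it was 1 (highest other 12), and within numbers 1 to 3 and 4 to 6 the counts were 1342 and 352. In ad libitum eWAT 2 of 100 were as high (491), the other being numbers 1 to 3 against 4 to 6 with 2053, beside 320 and 297 within these sets. In fasted eWAT 2 of 100 were as high (1704), up to 2632 for a split near these sets, and 1 of the 32 that part every pair (highest other 46). The sets gave 1279 and 739 there. These splits show the same structure of the libraries by number. For the interaction 5 of 100 draws called as many as the 1 gene in iWAT (highest other 65), so chance is not excluded, and 4 of 100 as many as the 9 in eWAT (highest other 73).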
